A study of Picea abies with 19 samples.

How the data were processed

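Root ends of rooted Norway spruce (Picea abies) cuttings were profiled on 19 spotted oligonucleotide arrays, 1 array per sample, each hybridised with amplified RNA labelled with Alexa 647. Per the labels, the roots came from 8 genotypes whose sample titles begin with Fast or Slow, and were collected 5 or 18 months after adventitious roots had formed. The labels do not say what was fast or slow, and the classes are called growth classes here. The labels describe the samples of a genotype as biological samples of several root ends each. At 18 months the arrays of 1 genotype share the middle number of their titles. What that number stands for is not given in the sources used here. Any unit it marks cannot be told apart from genotype at that age.

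The deposited scanner files hold intensity values per the file headers: for each of 34992 spots, the median pixel intensity of the spot and of its local background, with no normalisation. The image software is not given in the sources used here. Of these spots, 32144 carry a spruce probe, each present once, and 2848 are controls. The columns of 1 file, slow 18-month replicate 1 (genotype 76), name a 532 nm channel, although that file, like the others, is named for 635 nm. The deposited table of the whole series holds log2 values, which the authors processed by steps that are not given in the sources used here. Its scale was read from the values: they are floored at 0, and where a column matches a scanner file the slope on the log2 net intensity lies between 0.756 and 1.02. Column medians of the table range from 1.43 to 5.08, so its columns as deposited do not share a common median. Whether its arrays were scaled before the values were floored cannot be read from these medians. Whether its values were centred in any other way, and how, stays unknown, and 0 of its columns lacked a sample.

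The table and the scanner files disagree on which sample is which. After quantile normalisation and centring of each probe, 11 of the 19 scanner files matched 1 table column each, at Pearson correlations across probes of 0.863 to 0.959, and in 11 of 11 cases that column bore the name of a sample of another genotype. Probes are not independent replicates, and a match was counted above a correlation of 0.8. No scanner file had the column of its own name as its best match. The highest correlation with the own column was 0.724, for slow 18-month replicate 2, which matched another column at 0.959. For the other 8 files the best correlation was at most 0.545. No sample was reassigned. The main results use the scanner files under their own labels, and the table is an alternative.

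In limma 3.58.1 under R 4.3.3, intensities were background-corrected with normexp and an offset of 50 over all spots. Control spots were then dropped, and log2 values were quantile-normalised over the 19 arrays. A probe was kept when its intensity exceeded the background by 2 background standard deviations on at least 4 arrays. This kept 16012 probes and left out 16132. Between 4944 and 18498 probes per array, 15.4 to 57.5 percent of the spruce probes, exceeded that level. The number of arrays limits the precision.

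Growth class was tested on genotype means of the 18-month cuttings, 4 genotypes against 4, since the class belongs to the genotype. Age was tested over all 19 arrays with genotype as a fixed term, so that the contrast rests on the 3 genotypes sampled at both ages. Genotypes were compared with limma's moderated F-test on the 15 arrays from 18-month cuttings. The interaction of age with growth class compares genotype 52 with genotypes 20 and 35. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a group was not well above background on any of its arrays, a fold is given as a bound. It sets the bright group's mean against, per dim array, the higher of the lowest signal among probes above background and the probe's own signal.

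Simulated arrays with the per-probe means and spreads of these data were used to test the fits on 16012 probes. In each, 100 probes were changed by 2 and 100 by 4 log2 units. For the genotype test no spread between genotypes was simulated beyond the changed probes. Noise was drawn independently for each probe and array, without scan effects, background floor, scanner maximum or outlying array. The counts below therefore hold for those settings and can differ in these data. For growth class, 63 of the 100 probes changed by 2 log2 units and 98 of those changed by 4 were recovered, with 8 unchanged probes called. For age, 80 and 99 were recovered, with 8 unchanged probes called. With 1 genotype shifted, the genotype test recovered 4 and 86, with 8 unchanged probes called. The interaction recovered 4 and 68, with 1 unchanged probe called.

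Scan timing was read from the files as 9 scan days in 3 scan periods. The 2 arrays of genotype 76 make up the late period, so this genotype and that period cannot be told apart. Alternatives named before the data were examined covered background correction, offset, scaling, the filter on dim probes, the authors' table, robust eBayes, the handling of genotype, replicate number and scan period, and left-out genotypes and arrays. Alternatives without single doubted arrays, within scan periods, with scan day as a random block and with the table quantile-normalised were added after seeing the data. A further 26 combinations of the table values with other designs were looked at. They gave 0 to 6 probes for growth class, 0 to 1059 for age and 0 to 3005 for genotype. A search for probes with separated low and high levels was tried and dropped without a test.

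The files do not pair probe IDs with gene names, so the 26 gene lists fixed beforehand could not be matched and no gene list was tested. The rule for named probes, fixed beforehand, then allows at most 2 probe IDs per direction and comparison, those of smallest p. The genotype test has no direction, and its 4 probes of smallest p are named.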

Results

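Transcript levels were measured in root ends of Norway spruce cuttings of 8 genotypes. Cuttings of 18 months gave 7 arrays from the fast genotypes 15, 18, 20 and 35 and 8 arrays from the slow genotypes 52, 61, 70 and 76. Cuttings of 5 months gave 2 arrays from fast genotypes (20 and 35) and 2 arrays from slow genotype 52. Genotype 15 had 1 array, and the other genotypes had 2 arrays each at 18 months. Values are normalised log2 intensities, and the number of arrays limits their precision. Probes carry no gene name in the files and are given by ID.

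All directions below are those of the scanner files under their own labels. The authors' table puts 11 of the 19 arrays under the name of another genotype, and the slow minus fast differences from both sources correlated at -0.02 across 16012 probes, with 48.1 percent of the same sign. For the age difference the correlation was 0.35, with 62.3 percent of the same sign. Some of the 11 matches also crossed growth class or age. Fast 18-month replicate 4 matched the column of slow 18-month replicate 4, and slow 5-month replicate 2 that of fast 18-month replicate 5. The sources thus differ in class and age labels as well as in processing. Probes are not independent replicates.

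**Figure D1:**
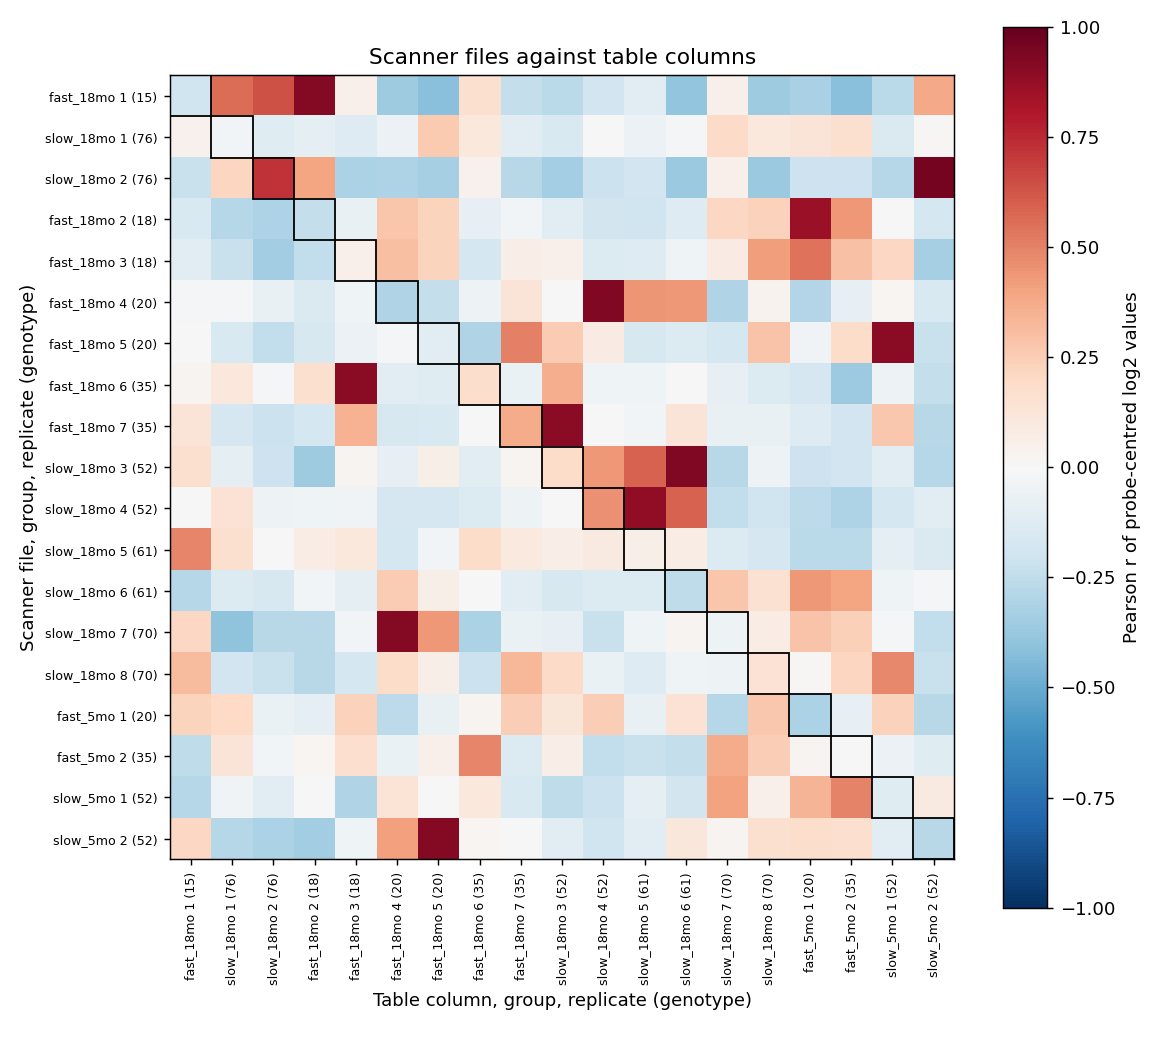
Pearson correlation (colour) of probe-centred log2 values between each scanner file (vertical axis) and each column of the authors' table (horizontal axis), with genotype in brackets and same-named pairs boxed. In 11 files a single column reaches 0.863 or more, and none of these is the boxed one.

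The comparison of 8 genotypes asks which transcripts differ between genetic backgrounds in roots of 18-month cuttings. By limma's moderated F-test, 92 of 16012 probes passed an adjusted p of 0.05, and 2457 had an unadjusted p below 0.05 where 800.6 would be expected by chance. On 59 of the 92 probes at least 1 genotype was not above background on any of its arrays, so the spans of the genotype means are bounds. With such genotypes set at the lowest detected signal, the span had a median of 3.65 log2 units, from 1.64 to 6.90, and 36 probes spanned at least 4 log2 units. The p-values of the probes named next are those of the F-test over 8 genotypes. The genotypes set against each other are the extremes, and these pairs were not tested.

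Spruce_16443 was not well above background on any array of genotype 20, with means of 6.64 ± 0.43 (SD, n = 2) at 18 months and 6.90 on the single 5-month array. It reached 13.81 ± 0.27 (SD, n = 2) in genotype 18, at least 79.8-fold higher (F-test over 8 genotypes, adjusted p = 0.00139, limma). Spruce_26690 was above background in genotypes 15 and 35 alone of the 8. Its value was 12.05 on the single array of genotype 15, 11.08 ± 0.21 (SD, n = 2) in genotype 35 at 18 months and 11.69 on the 5-month array of that genotype. Genotype 61 had the lowest mean, 6.00 ± 0.08 (SD, n = 2), but the order among genotypes not above background carries no meaning. The single array of genotype 15 was at least 16.9-fold higher than genotype 61 (F-test over 8 genotypes, adjusted p = 0.000437, limma).

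Spruce_27873 was lowest in genotype 61, at 8.62 ± 0.49 (SD, n = 2, 1 array above background), and highest in genotype 70, at 15.52 ± 0.67 (SD, n = 2; F-test over 8 genotypes, adjusted p = 0.000644, limma). Since 1 of the genotype 70 arrays read the scanner maximum and 1 of the genotype 61 arrays was not above background, no fold is given. Spruce_16982 was above background in genotypes 20, 35 and 70. It reached 11.81 ± 0.01 (SD, n = 2) in genotype 70, at least 7.84-fold above the 6.88 ± 0.01 (SD, n = 2) of genotype 76 (F-test over 8 genotypes, adjusted p = 0.00139, limma). The arrays of genotype 76 are the one with the deviating channel name and the one least like the others. Genotypes 15, 18, 52 and 61 were not above background either. With all such genotypes at the lowest detected signal, the span of this probe was 4.42 log2 units, against 2.97 for genotype 76 alone.

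**Figure D2:**
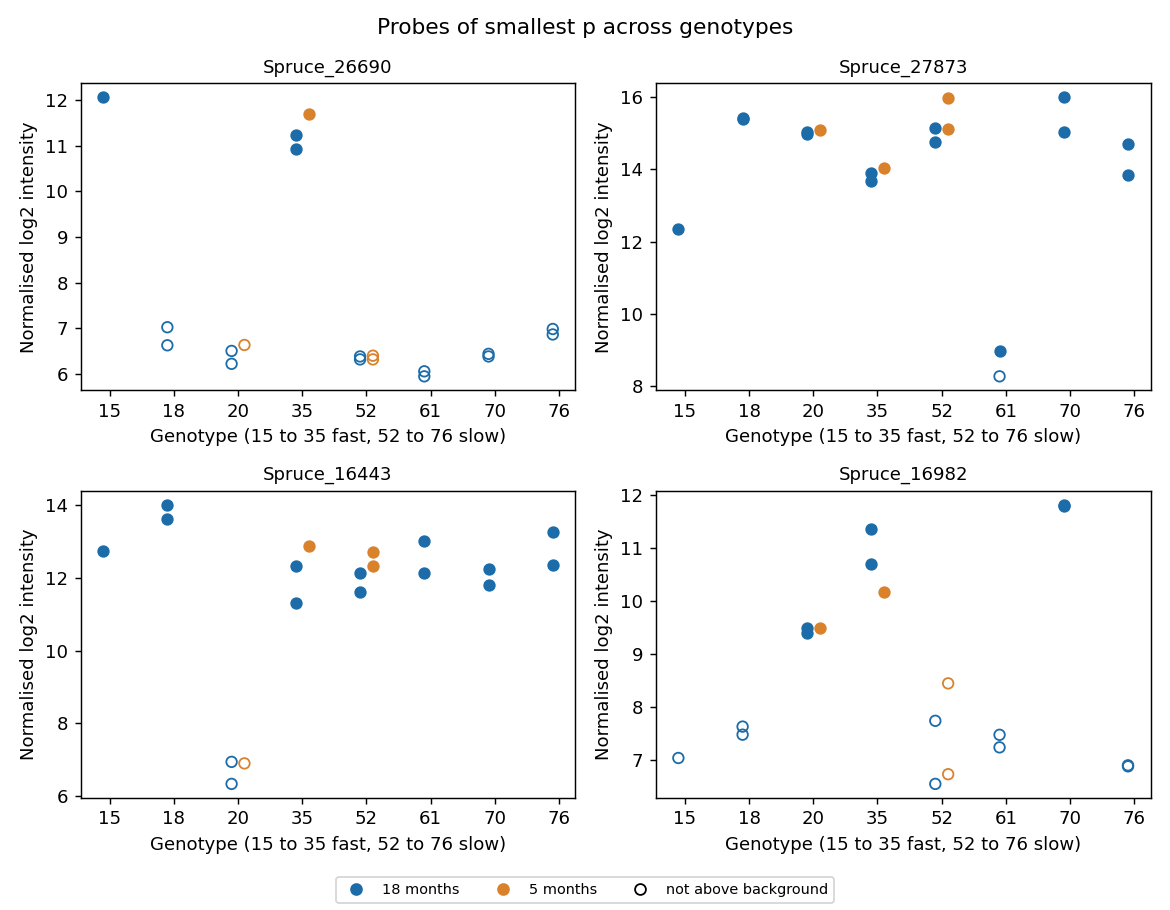
Normalised log2 intensity (vertical axes) of the 4 probes of smallest p in the genotype test, by genotype (horizontal axes). Each point is 1 array, blue at 18 months and orange at 5 months, and open where not above background. Spruce_16443 lies between 6.33 and 6.94 on the 3 arrays of genotype 20 over both ages.

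The 5-month arrays did not enter the genotype test, but the filter on dim probes and the normalisation ran over all 19 arrays. Spruce_26690 met the filter of 4 arrays only with a 5-month array. Genotype 52 minus the mean of 20 and 35 had the same sign at both ages in 70 of 92 probes, with a correlation of 0.66 across these probes. For genotype 35 against the others 73 of 92 had the same sign (0.80), and for genotype 20 71 of 92 (0.79). Over all 16012 probes the same sign was found in 58.4, 56.6 and 51.0 percent, and the correlations were 0.27, 0.29 and 0.16. These contrasts share the same arrays and are not independent of each other, and genotypes 20 and 35 each had 1 array at 5 months. Probes are not independent replicates.

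The count of 92 depended on the genotypes in the test. It was 32 without genotype 18, 41 without 35, 39 without 52 and 48 without 70. The arrays of genotype 76 alone were scanned in the late period and include the array least like the others. Genotype 76 was also the one farthest from the mean over genotypes on 24 of the 92 probes, the most of any. Genotype 15 followed with 15 probes. Without genotype 76, 581 probes passed, 83 of them among the 92, and with scan period as a term as well 432 passed, 80 of them among the 92. Without slow 18-month replicate 1 alone, 5360 passed, and without slow 18-month replicate 2 alone, 484. Random groupings of all 15 arrays gave as many probes in 11 of 100 groupings, the real one included, as set out in the closing section.

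The comparison of growth classes asks whether roots of fast and slow genotypes differ in transcript levels at 18 months. In limma on genotype means, 0 of 16012 probes passed an adjusted p of 0.05 in either direction, and the lowest adjusted p was 1.00. At an unadjusted p below 0.05 there were 394 probes, 129 higher and 265 lower in the slow class, fewer than the 800.6 expected by chance. Leaving out 1 genotype moved this count between 231 (without 35) and 600 (without 18). With scan period as a fixed term and genotype as a random block it was 837. The median 95 percent interval reached 0.87 log2 units to either side, and for 5276 probes the whole interval lay within 1 log2 unit of no difference. For the remaining probes a difference of that size was not excluded. Only 2796 probes were above background on every array of this fit, so the 5276 include probes with readings not above background. On such readings the background and the offset limit the difference and the spread that can be seen. For those probes a narrow interval does not exclude a difference of that size in transcript level.

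The probes of smallest p did not pass. Spruce_29384 was 10.67 ± 0.64 in the fast and 8.49 ± 0.51 in the slow class (SD, n = 4 genotypes each), a fitted difference of -2.19 ± 0.40 (SE, adjusted p = 1.00, limma). It was above background on 7 of 7 fast arrays and on 5 of 8 slow arrays, so part of the slow level lies near background. Spruce_20749 was 9.06 ± 0.40 in the fast and 7.49 ± 0.10 in the slow class (SD, n = 4 genotypes each). It was above background on 5 of 7 fast arrays and on 1 of 8 slow arrays, so the slow level lies near background. Spruce_01742 was 10.29 ± 0.49 in the fast and 11.87 ± 0.51 in the slow class (SD, n = 4 genotypes each), with a difference of 1.57 ± 0.37 (SE). Spruce_06215 was not well above background on any of the 7 fast arrays and was above it on 3 of 8 slow arrays, so no fold is given. Within scan period 1 and within scan period 2, 0 probes passed. With scan period as a fixed term and genotype as a random block, 2 probes were lower in the slow class. They were Spruce_29384 (adjusted p = 0.0377, limma) and Spruce_02904, the latter named after its value was seen. The fitted correlation within genotypes was -0.054 there, so arrays of a genotype were in effect counted as independent. Without the scan term it was 0.22, and Spruce_29384 did not pass (adjusted p = 0.0936, limma). Both probes are also among those that passed the genotype test.

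The comparison of ages asks which transcripts differ between roots of 18 and 5 months. In limma with genotype as a term, 0 of 16012 probes passed an adjusted p of 0.05, and the lowest adjusted p was 0.158. At an unadjusted p below 0.05 there were 1404 probes, 680 higher and 724 lower at 18 months, where 800.6 would be expected by chance. That count moved with the design. It was 306 with no genotype block, 607 with genotype as a random block and 1072 with scan period as a term. Over only the 3 genotypes sampled at both ages it was 2150. The median 95 percent interval reached 0.83 log2 units to either side, and for 4671 probes it lay within 1 log2 unit of no difference. Only 2613 probes were above background on every array of this fit, so the 4671 include probes with readings not above background. For those probes a narrow interval does not exclude a difference of that size in transcript level.

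Spruce_02805 had a fitted difference of 5.30 ± 0.93 log2 units between 18 and 5 months (SE, adjusted p = 0.158, limma), which rests on readings at both ends of the scale. In genotypes 20, 35 and 52 it was 15.64 ± 0.48 (SD, n = 6, 1 array at the scanner maximum) at 18 months and 10.29 ± 3.37 (SD, n = 4) at 5 months. The 5-month arrays of scan period 1 read 13.06 and 13.33 and were above background, and those of scan period 2 read 7.65 and 7.11 and were not. Within scan period 1 the difference was 2.21 (adjusted p = 0.0355, limma). Spruce_02899 was above background on 6 of 6 arrays of these genotypes at 18 months, 10.54 ± 0.81 (SD), and on 0 of 4 at 5 months. Its mean over these arrays was at least 4.35-fold higher at 18 months, a bound that carries no sampling error, and the probe did not pass (adjusted p = 0.158, limma; 0.0507 within scan period 1). Among genotypes sampled at 18 months only, it was above background on 1 of 1 array of genotype 15 and 1 of 2 each of 61 and 70. On the arrays of genotypes 18 and 76 it was above background on 0 of 2 each.

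Spruce_07739 was 9.21 ± 1.18 (SD, n = 6) at 18 months and 11.32 ± 0.80 (SD, n = 4) at 5 months, with a difference of -2.34 ± 0.39 (SE, adjusted p = 0.158, limma). Within scan period 1 the difference was -2.74 and passed (adjusted p = 0.0159, limma). Spruce_16299 was 9.18 ± 0.27 (SD, n = 6) at 18 months and 11.21 ± 1.39 (SD, n = 4) at 5 months, with a difference of -2.08 ± 0.42 (SE, adjusted p = 0.278, limma). Its 5-month arrays read 10.41 and 9.67 in scan period 1 and 12.58 and 12.17 in scan period 2, and within scan period 1 the difference was -0.81 (adjusted p = 0.224, limma).

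**Figure D3:**
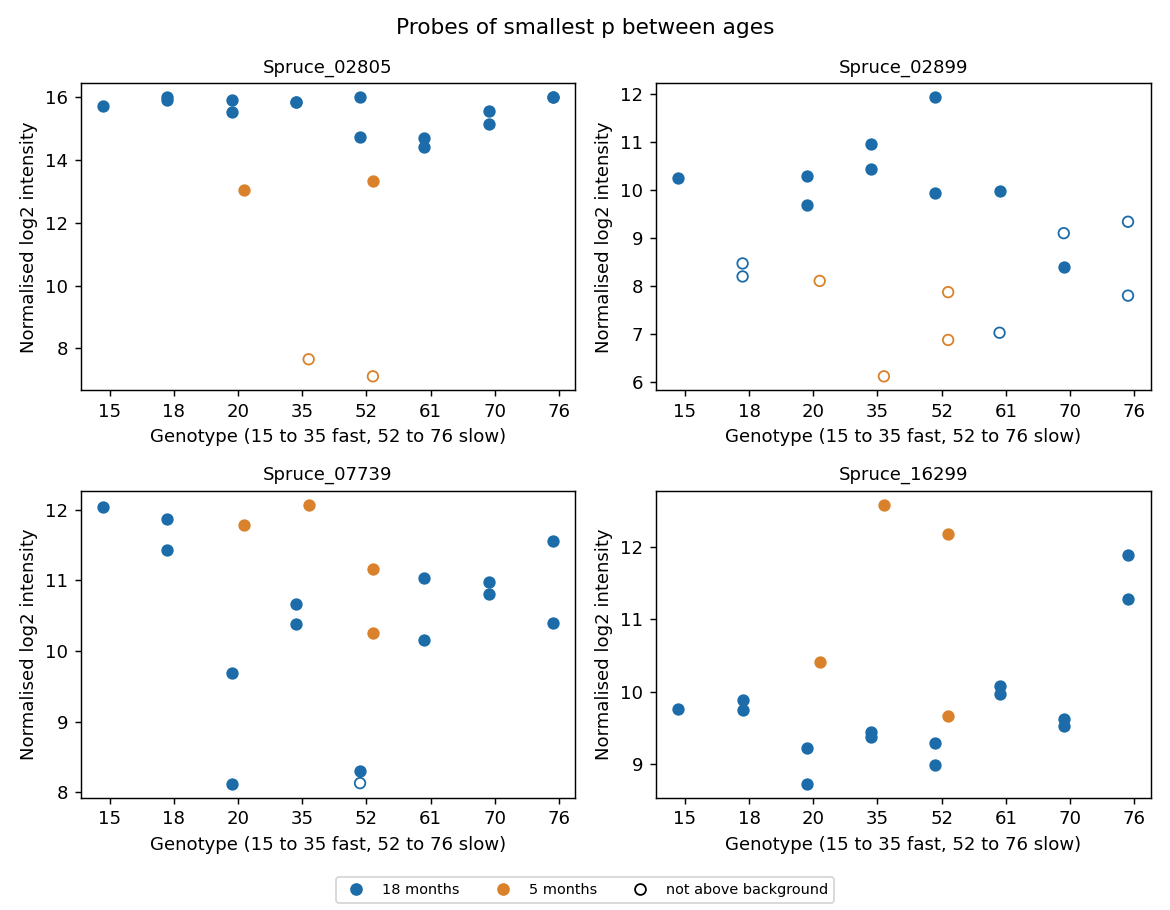
Normalised log2 intensity (vertical axes) of the 4 probes of smallest p between ages, by genotype (horizontal axes). Each point is 1 array, blue at 18 months and orange at 5 months, and open where not above background. The 5-month arrays of Spruce_02805 lie at 7.11, 7.65, 13.06 and 13.33.

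With scan period as a fixed term 0 probes passed for age. Within scan period 1, where genotypes 20 and 52 each had 1 array at 5 months, 341 probes passed, 54 higher and 287 lower at 18 months. There the 18-month arrays of these genotypes were all scanned on day 4 and the 5-month arrays on days 1 and 2, so age and scan day cannot be told apart. With scan day as a random block over all arrays 0 probes passed. Without fast 18-month replicate 5, 29 probes passed, 6 higher and 23 lower, and without slow 5-month replicate 2, 2 passed.

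The interaction asks whether the age difference differs between growth classes, here between genotype 52 and genotypes 20 and 35. In limma, 0 of 16012 probes passed an adjusted p of 0.05, and 484 had an unadjusted p below 0.05 where 800.6 would be expected by chance. The lowest adjusted p was 0.999. Spruce_20571 was 12.78 ± 0.65 at 5 months and 9.76 ± 0.15 at 18 months in genotype 52 (SD, n = 2 each), and at 5 months it was not well above background in genotypes 20 and 35. At 18 months it was 9.07 ± 0.03 in genotype 20 and 9.94 ± 0.44 in genotype 35 (SD, n = 2 each). Spruce_30742 was 15.13 ± 0.68 at 5 months and 10.08 ± 0.26 at 18 months in genotype 52 (SD, n = 2 each). In genotype 20 it read 14.27 at 5 months, and at 18 months 11.75 on fast replicate 4 and 15.05 on fast replicate 5. In genotype 35 it was 15.48 at 5 months (n = 1) and 14.92 ± 0.19 at 18 months (SD, n = 2). Its interaction of -4.33 ± 0.99 (SE, adjusted p = 0.999, limma) passed when fast 18-month replicate 4 was left out, at -5.06 (adjusted p = 0.0473, limma).

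Spruce_26342 was 7.44 ± 0.60 at 5 months, not well above background, and 9.57 ± 0.30 at 18 months in genotype 52 (SD, n = 2 each). It was 11.05 at 5 months and 9.82 ± 0.81 at 18 months in genotype 20 (SD, n = 1 and 2). In genotype 35 it was 9.34 and 8.27 ± 0.39 (SD, n = 1 and 2). Its interaction was 3.28 ± 0.78 (SE) and did not pass. Spruce_10935 was 8.31 ± 0.54 at 5 months, not well above background, and 9.59 ± 0.66 at 18 months in genotype 52 (SD, n = 2 each), against 10.43 at 5 months and 8.74 ± 0.25 at 18 months in genotype 20 (n = 1 and 2).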

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

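The tests of scan period, of array brightness at the adjusted threshold, of the least similar array, of probe sequence and of the genotype names were chosen after the results they bear on had been seen, and the regroupings without genotype 76 after the regrouping of all 15 arrays had been run.

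Slow 18-month replicate 2 (genotype 76) stood far from its group in mean Spearman correlation with the other arrays, at 0.395 against 0.709 for the next. It also stood apart in the median net intensity of the GFP1 control spots, at 1799 against 719.7 for the next, and of the GFP2 control spots, at 2261 against 748.4. Fast 18-month replicate 1, the single array of genotype 15, had the lowest mean Spearman correlation of its group, 0.691 against 0.763 for the next. Spruce_30742 read 11.75 on fast 18-month replicate 4, against 14.72 for the next array of that group. These are 5 flags from 42 groups tested, and chance flags about 1 in 20 groups. Of the control spots, 60.2 percent of GFP1 and 53.6 percent of GFP2 readings were above background, against 0 percent for the spots named GFP alone and for Alien, empty, buffer and blank spots, and what these controls were hybridised with is not given in the sources used here.

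The 92 probes that differed between genotypes were set against regroupings of the 15 arrays. In 11 of 100 groupings, the real one included, as many probes passed, and the highest other grouping gave 3473, so chance is not excluded by this count. Of the 10 other groupings with as many probes, 7 left slow 18-month replicate 2 alone in its group, which points to the structure that array brings. In all, 7 of the 99 random groupings left it alone, and each of these gave as many probes as the real one. With that array paired, as in the real grouping, the most was 257 probes, still above 92. Without genotype 76, 1 of 100 groupings, the real one, gave as many as 581 probes and the highest other gave 36. These groupings break up scan periods, which the real one partly keeps. With names permuted only within scan periods, again 1 of 100 gave as many and the highest other gave 218. That is the smallest share so few regroupings can give. It argues against chance for the count of 581, not for the 92 probes. Scan days were not kept together, and genotype 76 was left out only after the regrouping of all 15 arrays.

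Scan period and the least similar array were argued against as the whole cause of the 92 probes. With scan period as a term and genotype 76 left out, 80 of 92 passed the adjusted threshold, and without the least similar array 90 of 92 passed. Brightness of the arrays stays open. With the share of probes above background as a term, 92 of 92 kept an unadjusted p below 0.05, but that is laxer than the threshold the probes were chosen by, at which 52 of 92 passed. It also stays open whether a probe differs because the transcript level does or because the genotype's sequence under the probe does. On 59 of the 92 probes 1 genotype was undetected on all its arrays and another detected on all, but 6789 of 16012 probes were like that, and probe sequences were not used here. A transcript difference between genotypes therefore remains a hypothesis.

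The conflict between scanner files and table was tested by leaving out each of 18 arrays in turn, choosing 50 probes from the rest and placing the array in the nearest genotype. Under the scanner files' names 16 of 18 arrays were placed in their named genotype, against at most 7 in 99 permutations of the names. Of the 16 arrays with no array of the same genotype scanned on the same day, 14 were placed correctly. Under the table's names 3 of 18 columns were placed correctly, and 27 of 100 namings, the real one included, did as well, with at most 7. Among the 3 were both columns named genotype 61, which matched the 18-month scanner files of genotype 52 (correlations of 0.889 and 0.926). Arrays of 1 genotype were also more alike under the scanner files' names (mean correlation 0.12 against -0.06, permutation p = 0.00365, adjusted p = 0.00608). With names permuted only within scan periods the permutation p was 0.00068 (adjusted p = 0.0017). Columns of 1 genotype were more alike under the table's names as well (0.08 against -0.06, permutation p = 0.0192, adjusted p = 0.0240), so these tests leave open whether the table's names carry information on genotype. That the scanner files' names carry none is excluded, which does not show that each name is right.

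For growth class, 26 of the 35 splits of the 8 genotypes gave at least the 394 probes at an unadjusted p below 0.05, and the highest other split gave 2092, so chance is not excluded. For age, 4 of the 54 reassignments of arrays within genotypes gave at least 1404 such probes, and the highest other gave 2265, so chance is not excluded. Within scan period 1 the 6 reassignments are too few for a share under 0.05: the real one gave 341 probes past the adjusted threshold (1 of 6) and the highest other gave 0, and age goes with scan day there. The unadjusted counts were used for growth class and age because 0 probes passed the adjusted threshold.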

How the results depend on the processing

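Growth class, age and the interaction kept a count of 0 probes in 22 of 25, 22 of 29 and 18 of 19 alternatives, identical fits counted once. The table as deposited gave 3 probes for growth class (Spruce_31089, Spruce_00417 and Spruce_12261, named after their values were seen) and 2702 for genotype against 92. The table quantile-normalised, added after seeing the data, gave 0 for growth class, 1 for age (Spruce_12343) and 3 for genotype. Treating the 15 arrays as independent gave 1 probe for growth class (Spruce_29384). Scan period with genotype as a random block, where the fitted genotype correlation was -0.054, gave 2. With the last title number as a replicate block 0 probes passed for growth class and 0 for age. What this number stands for is not given in the sources used here. Deviations correlated above 0.1 in 2 of 9 same-numbered pairs of fast and slow arrays and in 13 of 47 other pairs. So few pairs cannot show whether the number marks a block. For age, no genotype block, genotype as a random block, and leaving out the genotype 52 arrays whose titles end in 6a (18 months) and 6b (5 months) each gave 1 probe (Spruce_02805). These titles share a number, and whether both arrays come from 1 plant is not given in the sources used here. For genotype, the strict filter gave 12 probes (2796 tested), leaving out genotype 76 gave 581, scan period as well 432, and all 19 arrays with age 246. Added after seeing the data, leaving out the least similar array gave 484, leaving out the array with the deviating channel name gave 5360, where the outlying array is then the only one of its genotype, and age within scan period 1 gave 341.

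Leaving out 1 genotype at a time gave 0 probes throughout for growth class and 32 to 581 for genotype. Leaving out 1 array at a time gave 0 to 29 for age and 0 to 1 for the interaction. Named probes changed sign only with the table. Since the table differs in sample names as well as in processing, these changes cannot be put down to processing alone. As deposited it gave -0.0925 for Spruce_01742, -0.65 for Spruce_06215, 0.60 for Spruce_29384, 0.0154 for Spruce_20749, 0.13 for Spruce_07739, 1.04 for Spruce_16299, 1.10 for Spruce_20571 and 1.88 for Spruce_30742. Quantile-normalised it gave -0.57 for Spruce_06215, 0.79 for Spruce_29384, 0.0545 for Spruce_20749, -0.37 for Spruce_26342, -1.06 for Spruce_10935 and 0.42 for Spruce_30742. Where not stated, the cause was not tested. The gene lists and their alternatives were not run. Signal over background limits the dim probes.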

Other observations

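The arrays resembled each other by scan timing as well as by genotype. Arrays of 1 scan period had a mean correlation of probe-centred values of 0.06 and arrays of different periods -0.11 (permutation p = 0.00034, adjusted p = 0.0017 over 5 such tests). Within periods, arrays of 1 scan day were more alike (permutation p = 0.0327, adjusted p = 0.0327). The first principal component, with 32.4 percent of the variance, set slow 18-month replicate 2 (score -217.2) apart from the other arrays (-63.5 to 38.3).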
